A study of Danio rerio with 20 samples.

How the data were processed

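Wild-type zebrafish larvae were exposed from 4 to 5 days post fertilisation, and each library came from a pool of 10 whole larvae, per the labels' protocols. Libraries were stranded mRNA libraries with unique molecular identifiers, read in pairs on a NovaSeq instrument. The deposited values were taken as raw count values per gene, since all were whole numbers and the submitters' processing notes speak of counts. Reads had been aligned with STAR 2.7.8a to zebrafish genome build GRCz11 after demultiplexing with CASAVA, with SAMtools, and DESeq2 named with version 3.17, per the submitters' processing notes. The counting tool, the annotation release and whether molecular identifiers were collapsed are not given in the sources used here. No genome sequence was used, so genes are given by symbol and Ensembl identifier as in the count table and no coordinates are given. The table held 32520 genes; 1234 carried a symbol used more than once, were kept apart by identifier and are named as uncertain where they appear, and 865 had no symbol. The per-sample files equalled the table of the series for 20 of 20 libraries, so that alternative had nothing to change. cyp19a1b carried the biotype of an unprocessed pseudogene in the table, and its counts were used like those of any other gene.

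Tests, groups, gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Genes were kept with edgeR's filterByExpr on the 4 groups with a minimum count of 10, which left 23121 genes and removed 9399; the kept genes held at least 99.97% of each library's counts. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion) in R 4.3.3, with all 20 libraries in a single fit of 4 group means and no block. The contrasts were SEC minus CTRL in JUN20, the same in OCT20, the OCT20 effect minus the JUN20 effect, and CTRL OCT20 minus CTRL JUN20; the difference and the control contrast share the control libraries. The contrast of SEC OCT20 against SEC JUN20 was added after the data were seen. P-values were two-sided, adjusted with the Benjamini-Hochberg method over all tested genes and called under 0.05 with no fold threshold. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. CPM values are TMM-normalised, with means and SD over 5 libraries, except in the plot of the 5 October genes. The overlap of both campaigns was tested with a one-sided Fisher's exact test per direction against the number that independent lists give.

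Gene lists of zebrafish symbols were fixed by hand from general knowledge and matched to the table, 1022 of 1042 members in all, 19 of them through the reference table of symbols. The 37 lists were aryl hydrocarbon receptor targets, Nrf2 and oxidative stress, other xenobiotic metabolism and transport, glucocorticoid response, estrogen response, thyroid axis, retinoid signalling, fatty acid oxidation and PPAR targets, cholesterol synthesis, fatty acid synthesis, bile acid metabolism, heat shock response, unfolded protein and ATF4 response, p53 response, cell cycle, photoreceptor and phototransduction, lens, exocrine pancreas, hepatocyte plasma proteins, enterocyte, complement and acute phase, inflammation and leukocytes, interferon response, extracellular matrix and cartilage, skeletal muscle, cardiac muscle, neuron, glia and myelin, immediate early genes, circadian clock, hypoxia response, erythrocyte and haem synthesis, epidermis and keratins, ionocytes, pigment cells, mitochondrially encoded genes and cytosolic ribosomal proteins. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom-weighted log2 CPM with a preset correlation between genes of 0.01, adjusted over the 37 lists. The same test with a correlation estimated from the data and limma's fry, with its mixed form, were run beside it. Members were also adjusted over their list alone.

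The named genes were, per campaign, the 8 higher and 8 lower genes with the smallest adjusted p among those with a mean of at least 1 CPM, without genes named only by a clone or locus. Up to 4 members with the smallest p of each list past the threshold were added, as were 14 indicator genes whatever their values. For the difference and the control contrast the 5 genes with the smallest adjusted p in each direction were taken, and for the overlap the 10 with the smallest larger adjusted p. Of list members that the rule took, the text gives those with the smallest p first, and some are not reported here. Genes outside the rule are named as such in the text.

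Alternatives were DESeq2 1.42.0 (Wald test, own size factors and filtering), RLE factors or library totals alone in place of TMM, no filter except genes with 0 in all libraries, a stricter filter (1 CPM in 5 libraries and a summed count of 200), the replicate number within each campaign as a block (10 blocks), each library left out in turn, and only the libraries compared in the fit. A term for the division of the October libraries by 5 genes, and fits within each side of it, were added after the data were seen. A gene counted as dividing the libraries of a campaign when a gap of at least 2 on the log2 scale, wider than all other steps of its range together, separated both sides and each side held both groups. Libraries were checked for copies by comparing every pair of a group, 40 pairs in all, and the lowest chi-squared per degree of freedom was 5.44, so none was a copy of another. Each main count was compared with those from 100 divisions of the same libraries into groups of the same sizes, the real one included.

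The steps were tested on simulated data, negative binomial counts drawn with the control means and the dispersions and library sizes of the real libraries, with known changes put into genes chosen at random. With changes of 0.5, 1 and 2 on the log2 scale, in 67, 67 and 66 genes for each campaign and the controls, edgeR recovered 74.6%, 95.5% and 100% of genes in JUN20, 67.2%, 91.0% and 100% in OCT20, 56.1%, 85.1% and 99.2% for the difference and 73.1%, 97.0% and 100% between controls. False calls were 2.70%, 6.52%, 4.78% and 3.74% of the calls in the same order with edgeR, and 8.87%, 13.2%, 10.2% and 10.6% with DESeq2. The simulation used the same dispersion of a gene in all groups and had no October division, so these rates may not hold in the real OCT20 libraries. A shift of -0.5 in the 28 cell cycle genes was found by camera (adjusted p = 1.02e-27) and 0 other lists passed. The simulated genes were drawn without correlation between them. In the real OCT20 libraries the estimated correlation of the cell cycle list was 0.817. The simulation therefore cannot show how many lists camera passes by chance in real libraries at the preset correlation. At that setting other divisions of the OCT20 libraries passed up to 26 lists. The division with 26 kept all but 1 SEC library together and so much of the real contrast, and it is no figure for chance.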

Results

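Transcripts were counted in whole wild-type zebrafish (Danio rerio) larvae at 5 days post fertilisation. The larvae had been kept from day 4 to day 5 in water with an extract of the secondary effluent of a wastewater treatment plant (SEC), at a strength that the labels give as 20x. Extracts from 2 sampling campaigns, named JUN20 and OCT20, were each tested beside a control group (CTRL) of their own. Each of the 4 groups held 5 replicates, and each replicate was a pool of 10 larvae. The series' title places the effluent extracts in a study of effluent detoxification by soil aquifer treatment. The 20 libraries held 28.8 to 59.9 M counts (M for the sixth power of 10) each. Totals ran from 29.6 to 49.0 M in CTRL JUN20, from 35.3 to 59.9 M in SEC JUN20, from 28.8 to 40.2 M in CTRL OCT20 and from 32.7 to 45.4 M in SEC OCT20. Of 32520 genes in the count table, 23121 were tested. The spread between pools of a group corresponded to a common biological coefficient of variation of 10%. Mitochondrial ribosomal RNA took 2.30% ± 0.361 of the counts in CTRL JUN20, 2.28% ± 0.225 in SEC JUN20, 2.76% ± 0.447 in CTRL OCT20 and 3.16% ± 0.155 in SEC OCT20 (SD, n = 5 each). Whether the pools came from separate spawns is not given in the sources used here, so each p-value measures the spread between pools of 10 larvae. That spread was estimated for each gene over all 4 groups together, so it is not the spread of the October pools alone. Log2 fold changes are given with their standard error, SEC minus CTRL unless stated, and adjusted p-values are from edgeR's quasi-likelihood test over all genes with 5 libraries per group.

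The JUN20 comparison asked which transcripts differed between larvae kept with the June extract and their controls. Brain aromatase and enzymes of the cytochrome P450 1 family showed the strongest evidence for an increase. The gene cyp19a1b (ENSDARG00000098360), the brain form of the enzyme that turns androgens into estrogens and itself an estrogen-responsive gene, rose from 0.623 ± 0.0408 to 18.6 ± 1.48 CPM (counts scaled to a library total of 1 M; SD, n = 5 each), 29.8-fold, a log2 change of 4.90 ± 0.10 (adjusted p = 4.47e-19). The gene cyp1a (ENSDARG00000098315), the classic target of the aryl hydrocarbon receptor, rose from 53.7 ± 3.84 to 455 ± 30.4 CPM, 8.47-fold, a log2 change of 3.08 ± 0.06 (adjusted p = 4.47e-19). Keratins and other skin genes were among the genes with the strongest evidence for a decrease, led by cyt1l, a type I cytokeratin, at -0.88 ± 0.09 (adjusted p = 2.03e-06). The other genes with the smallest p on the higher side were cyp1c1 (2.18 ± 0.05), hebp2 (1.48 ± 0.06), cyp1b1 (2.098 ± 0.106), ahrra, a repressor of the aryl hydrocarbon receptor (2.13 ± 0.12), cry5, a photolyase of the cryptochrome family (1.005 ± 0.059), and tspo, a mitochondrial outer membrane protein (0.83 ± 0.05). On the lower side they were krt15 (-0.82 ± 0.09), krt18a.2 (-0.67 ± 0.07), the retinol-binding protein gene rbp2a (-0.58 ± 0.06), the anion exchanger gene slc26a6 (ENSDARG00000055835, -0.84 ± 0.10), the desmosome gene pkp1b (-0.59 ± 0.07), the neuronal transcription factor gene neurod1 (-0.53 ± 0.06) and the clock gene arntl1a (-0.44 ± 0.05). The symbol slc26a6 is shared by 2 genes of the table, so its value is uncertain where reads could be split between copies.

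**Figure D1:**
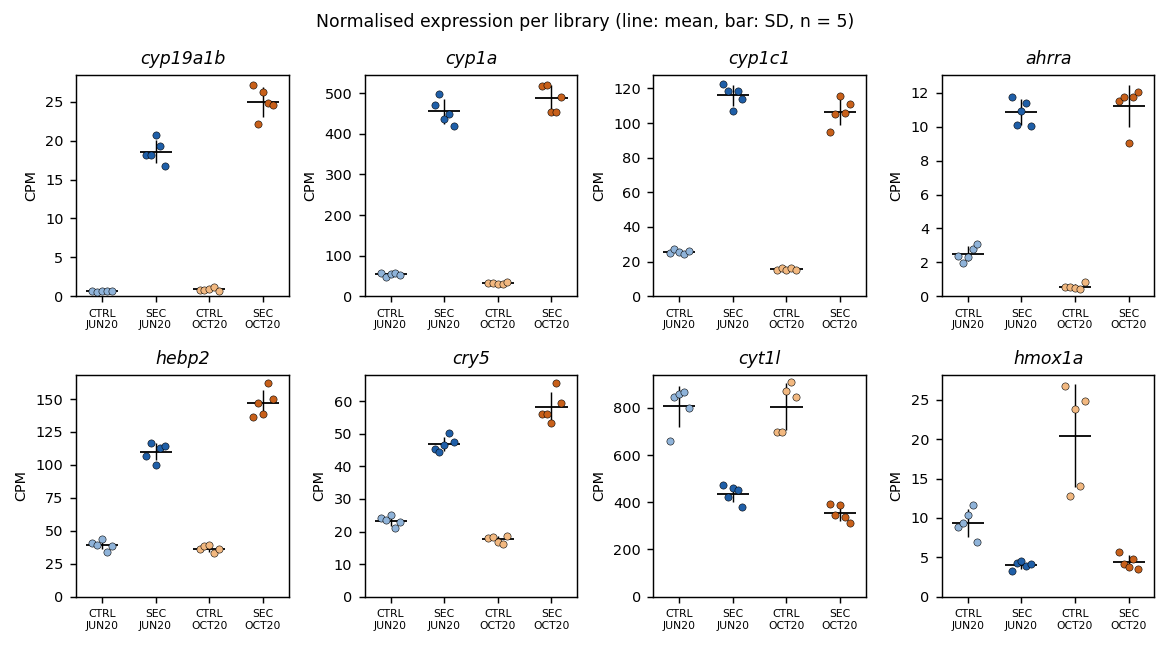
Normalised expression (CPM, linear axis from 0) of 8 genes in each of the 20 libraries, with 1 point per pool of 10 larvae, the horizontal line at the group mean and the vertical bar showing the SD (n = 5 per group). cyp1a averaged 53.7 CPM in CTRL JUN20, 455 in SEC JUN20, 31.6 in CTRL OCT20 and 487 in SEC OCT20, while hmox1a averaged 9.41, 4.00, 20.5 and 4.36 CPM in the same order.

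Of 23121 genes tested in JUN20, 2501 passed the adjusted threshold, 1368 higher and 1133 lower with SEC. Scaling by library totals alone moved the balance to 1800 higher and 724 lower. Most of these changes were small, with a median size of 0.299 on the log2 scale. In size, 89 genes were at least 2-fold higher and 34 at least 2-fold lower. All 5 SEC libraries lay above or below all 5 CTRL libraries for 2909 genes, where chance gives 0.794% of genes for groups of 5 and 5.

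Targets of the aryl hydrocarbon receptor, which senses planar aromatic compounds, rose as a group in JUN20. Of 11 measured members 9 rose and none fell, also 9 adjusted over the list alone, with a median log2 change of 1.48 (limma camera, adjusted p = 5.96e-27, and adjusted p = 1.77e-07 with an estimated correlation). Among them were the transcription factor gene foxq1a (1.48 ± 0.09) and the genes cyp1a, cyp1b1, cyp1c1 and ahrra given above. Genes of the Nrf2 pathway, which answers electrophiles and oxidants, rose in 17 of 24 measured members, or 18 adjusted over the list alone (camera adjusted p = 1.27e-15, and 0.000216 with an estimated correlation). Examples were the peroxiredoxin gene prdx1 (1.63 ± 0.13), the glutathione transferase gene gstp1 (0.74 ± 0.10) and the conjugate exporter gene abcc2 (0.98 ± 0.09). The member that fell was hmox1a, which encodes haem oxygenase and is induced by Nrf2 in other settings, at -1.23 ± 0.20 (adjusted p = 0.000519). Other genes of xenobiotic metabolism and transport rose in 15 of 31 measured members and fell in none, or 20 and 1 adjusted over the list alone (camera adjusted p = 2.79e-14, and 0.0339 with an estimated correlation). They included cyp2k18 (3.77 ± 0.24), cyp3a65 (0.87 ± 0.11), the efflux pump genes abcb5 (0.75 ± 0.06) and abcc4 (0.53 ± 0.06), and cyp2n13 (0.62 ± 0.07). Ionocyte genes, which encode the ion pumps and channels of the skin's salt-transporting cells, rose in 8 of 21 measured members, or 12 with 1 lower adjusted over the list alone (camera adjusted p = 1.15e-06, and 0.0339 with an estimated correlation). Among them were the sodium chloride cotransporter gene slc12a10.2 (0.76 ± 0.06), the sodium pump gene atp1a1a.3 (0.36 ± 0.05), the chloride channel gene clcn2c (0.51 ± 0.07) and the ammonia channel gene rhcgb (0.66 ± 0.09). The calcium channel gene trpv6, named after its values were seen, was the ionocyte member that fell (-0.41 ± 0.09).

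A further set of lists passed camera in JUN20 with the preset correlation of 0.01 and not with an estimated one. Epidermal genes fell in 11 of 29 members and rose in 1, or 15 and 1 adjusted over the list alone (adjusted p = 0.0594 with an estimated correlation). Both krt15 and krt94 (-0.40 ± 0.05) fell and the claudin gene cldne rose (0.29 ± 0.05). Photoreceptor genes fell in 13 of 43 members and rose in 1, or 23 and 1 adjusted over the list alone (adjusted p = 0.134 with an estimated correlation). The ultraviolet opsin gene opn1sw1 was at -0.56 ± 0.08, the cone transducin gene gngt2a at -0.52 ± 0.07 and the guanylate cyclase activator gene guca1g, named after its values were seen, as the member that rose (0.39 ± 0.07). Skeletal muscle genes fell in 15 of 46 members, or 21 with 1 higher adjusted over the list alone (adjusted p = 0.134 with an estimated correlation), such as the fast troponin gene tnni2a.1 (-0.28 ± 0.06). Fatty acid oxidation genes rose in 10 of 24 members and fell in 1, or 14 and 1 adjusted over the list alone (adjusted p = 0.0772 with an estimated correlation). Among them acadvl, an acyl-CoA dehydrogenase gene of the first step of the cycle, was at 0.42 ± 0.03, etfdh at 0.33 ± 0.05 and the acyl-CoA synthetase gene acsl1a, also named after its values were seen, as the member that fell (-0.28 ± 0.05). Genes of red cells and haem synthesis rose in 4 of 26 members, or 6 adjusted over the list alone (adjusted p = 0.488 with an estimated correlation). They were tspo, fech (0.68 ± 0.07), alas1 (1.05 ± 0.12) and 1 globin gene. The haem enzymes among them are made in many cell types. Heat shock genes rose in 7 of 24 members, or 14 with 1 lower adjusted over the list alone (adjusted p = 0.246 with an estimated correlation), led by the chaperone genes hsp70.2 (1.46 ± 0.26) and dnajb1b (0.85 ± 0.18). SEC replicate 5 stood apart at the level of the controls, with 17.3 CPM of hsp70.2 against 46.4 to 57.1 in the other SEC libraries and 12.3 to 18.7 in CTRL, and 14.9 CPM of dnajb1b against 24.6 to 35.2 and 10.6 to 17.6. The hypoxia list had 4 of 24 members higher, or 5 adjusted over the list alone (adjusted p = 0.236 with an estimated correlation). There hk2, the gene of a glycolytic enzyme, was at 0.77 ± 0.11 and hif1al at 0.47 ± 0.07.

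Lens genes fell in 6 of 49 members in JUN20, also 6 adjusted over the list alone, with lim2.4 at -0.22 ± 0.05 (adjusted p = 0.488 with an estimated correlation). Neuronal genes fell in 7 of 33 members, or 11 adjusted over the list alone, such as gad2, the gene of a GABA-synthesising enzyme (-0.19 ± 0.04; list adjusted p = 0.134 with an estimated correlation). Glial genes fell in 2 of 19 members, also 2 adjusted over the list alone, both myelin basic protein genes, with mbpb at -0.13 ± 0.03 (list adjusted p = 0.0594 with an estimated correlation). Enterocyte genes fell in 8 of 32 members and rose in 3, or 10 and 4 adjusted over the list alone (adjusted p = 0.686 with an estimated correlation). The glucose transporter gene slc5a1 was at -0.62 ± 0.09 and the ileal bile acid binding gene fabp6 at 0.68 ± 0.09. Retinoid genes fell in 5 of 19 members and rose in 1, or 6 and 2 adjusted over the list alone, with lrata, which encodes the enzyme that esterifies retinol for storage, at -1.51 ± 0.26 (list adjusted p = 0.488 with an estimated correlation). The cell cycle list passed as lower with 1 of 28 members lower, the mitotic checkpoint gene bub1 (-0.50 ± 0.13), also 1 adjusted over the list alone (adjusted p = 0.652 with an estimated correlation). The ribosomal protein list passed as lower (adjusted p = 0.738 with an estimated correlation) although the 1 of 75 members called was higher, rpl7l1 at 0.23 ± 0.06, with none adjusted over the list alone. The extracellular matrix list passed as lower with none of 38 members called, over all genes or adjusted over the list alone (adjusted p = 0.576 with an estimated correlation). The remaining lists did not pass, with camera adjusted p from 0.0625 for the unfolded protein and ATF4 response to 0.682 for hepatocyte plasma proteins and the circadian clock. They were glucocorticoid, estrogen, thyroid, cholesterol synthesis, fatty acid synthesis, bile acid, p53, exocrine pancreas, complement, inflammation, interferon, cardiac muscle, immediate early, pigment cell and mitochondrially encoded genes. In the estrogen list cyp19a1b was the 1 member of 8 that rose, and the egg yolk precursor gene vtg1 was at -0.76 ± 0.40 (adjusted p = 0.246). Median and mean differed in sign for the estrogen list (median -0.0571, mean 0.499, test up), the bile acid list (median -0.0441, mean 0.115, test up) and the hepatocyte list (median 0.0031, mean -0.0586, test down). Of the other indicator genes the clock gene per1a fell (-0.33 ± 0.10, adjusted p = 0.0469), a call that was lost under several other settings. The stress genes fkbp5 (-0.78 ± 0.27, adjusted p = 0.0753), hsp70l (1.02 ± 0.41, adjusted p = 0.125), mt2 (0.14 ± 0.10, adjusted p = 0.42) and cdkn1a (0.02 ± 0.20, adjusted p = 0.969) were not called.

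The OCT20 comparison asked the same of the October extract. The same gene families stood at the top. The gene cyp1a rose from 31.6 ± 2.2 to 487 ± 33.0 CPM, 15.4-fold, a log2 change of 3.95 ± 0.07 (SD, n = 5 each; adjusted p = 1.3e-20). Expression of cyp19a1b rose from 0.892 ± 0.179 to 25.01 ± 1.91 CPM, 28.3-fold, a log2 change of 4.82 ± 0.10 (adjusted p = 2.29e-19). Transcripts of ahrra rose from 0.563 ± 0.175 to 11.2 ± 1.25 CPM, 19.4-fold, a log2 change of 4.28 ± 0.15 (adjusted p = 1.1e-14). The other top genes on the higher side were cyp1c1 (2.76 ± 0.05), hebp2 (2.01 ± 0.06), cry5 (1.73 ± 0.06), porb, the gene of the reductase that feeds electrons to cytochromes P450 (1.39 ± 0.05), and tefa, a clock output transcription factor gene (1.07 ± 0.05). On the lower side they were krt18a.2 (-1.19 ± 0.08), pkp1b (-0.95 ± 0.07), slc26a6 (ENSDARG00000055835, -1.35 ± 0.10), ms4a17a.16 (-1.44 ± 0.11), slc5a1 (-1.20 ± 0.09), cyt1l (-1.18 ± 0.09), impdh1b, the gene of an enzyme of guanine nucleotide synthesis (-0.44 ± 0.04), and rx2, a retinal homeobox gene (-1.33 ± 0.12). Of 23121 genes tested 4168 passed, 2205 higher and 1963 lower, with a median size of 0.371. In size, 248 were at least 2-fold higher and 126 at least 2-fold lower. All libraries of one group lay above or below all those of the other for 2573 genes. In a fit with the October libraries alone the count was 2763, and in a fit with the June libraries alone the JUN20 count was 3666. Scaling by library totals alone turned the balance to 1985 higher and 2271 lower.

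The OCT20 libraries divided by 5 poorly described genes that were low or absent in 5 of the 10 libraries and higher in the other 5. The gene si:dkey-269o24.1, for example, had at most 29 counts in a library of the low side and at least 106 on the high side. The low side held CTRL replicates 1, 3 and 5 and SEC replicates 4 and 5, and the rule that found these genes took only divisions with both groups on both sides. The sides matched the sign of the first component of the deviations from group means, which held 44.3% of that variance over all 20 libraries, in 10 of 10 October libraries. The 5 genes that led this component on 1 side, named after their values were seen, were higher on the low side. Mean log2 CPM on the low and the high side was 7.318 and 6.395 for igfbp1b, 4.857 and 3.67 for ppp1r27b, 6.251 and 5.304 for klhl38b, 8.008 and 6.972 for trim63a and 7.272 and 6.331 for fbxo32. Within the low side 3273 genes were called and within the high side 4030, and 1698 were called in both with the same direction. The effect differed between sides past the adjusted threshold in 0 genes. At an unadjusted p under 0.05 it differed in 3171 of 23121 genes, more than the share of 0.05 expected without any difference. The 0 therefore does not show that the effects of both sides were equal. The change of cyp1a was 3.86 ± 0.09 on the low side and 4.03 ± 0.10 on the high side, against 3.95 pooled, and cyp19a1b was 4.90 ± 0.13 and 4.69 ± 0.15, against 4.82 pooled. Transcripts of hmox1a were at -2.63 ± 0.19 and -1.57 ± 0.18, against -2.24 pooled. Of the 5 genes that led the component, igfbp1b was at 0.16 ± 0.30 and 1.55 ± 0.33 and klhl38b at 0.02 ± 0.20 and 1.43 ± 0.225. The gene trim63a was at -0.02 ± 0.215 and 0.92 ± 0.225 and fbxo32 at 0.03 ± 0.24 and 1.12 ± 0.25, all called on the high side only. The gene ppp1r27b was at -0.67 ± 0.25 and 0.31 ± 0.28, called on neither. These 5 genes were picked for leading the component, along which the sides lay further apart in CTRL than in SEC. The choice itself therefore favours a more positive effect on the high side, and no effect particular to a side follows.

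**Figure D2:**
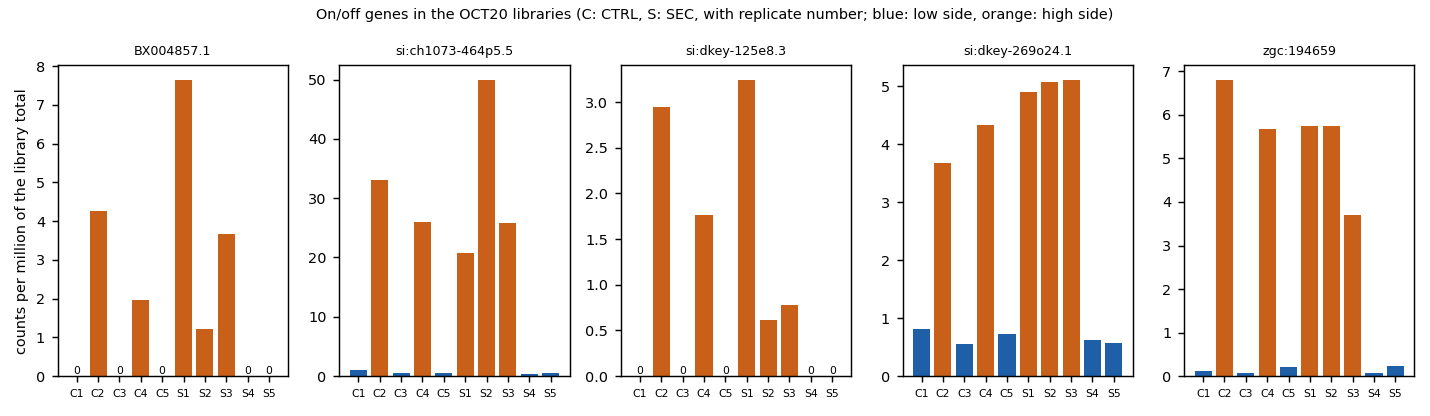
CPM of the library total (linear axis from 0) for the 5 genes in each OCT20 library, with C for CTRL and S for SEC followed by the replicate number, blue bars for the low side and orange bars for the high side. BX004857.1 and si:dkey-125e8.3 had 0 counts in all 5 libraries of the low side, and each side held libraries of both groups.

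In OCT20, 10 of 11 aryl hydrocarbon receptor targets rose, also 10 adjusted over the list alone, with a median log2 change of 1.95 (camera adjusted p = 1.79e-23, and 3.74e-07 with an estimated correlation). Among them cyp1b1 was at 2.73 ± 0.11 and foxq1a at 1.95 ± 0.10. Of the Nrf2 list 18 of 24 members rose, also 18 adjusted over the list alone (camera adjusted p = 5.88e-18, and 9.62e-05 with an estimated correlation). Examples were abcc2 (1.65 ± 0.09), nfe2l2a, which encodes Nrf2 (0.85 ± 0.05), and gclc, the gene of the rate-limiting enzyme of glutathione synthesis (0.87 ± 0.06). The gene hmox1a again fell, by 2.24 on the log2 scale with a standard error of 0.20 (adjusted p = 1.36e-07). Xenobiotic metabolism and transport genes rose in 18 of 31 members and fell in 2, or 21 and 2 adjusted over the list alone (camera adjusted p = 6.76e-15, and 0.0213 with an estimated correlation). Examples were cyp2k18 at 5.95 ± 0.26, cyp2n13 at 1.199 ± 0.073, cyp3a65 at 1.19 ± 0.11 and gstp1, of the Nrf2 list, at 0.93 ± 0.10. The members that fell, named after their values were seen, were the sulfotransferase gene sult1st2 (-1.32 ± 0.20) and the glutathione transferase gene gstt1a (-0.23 ± 0.07). Fatty acid oxidation genes rose in 14 of 24 members and fell in 2, or 17 and 2 adjusted over the list alone (camera adjusted p = 3.02e-12, and 0.0121 with an estimated correlation). Among them acadvl was at 0.74 ± 0.03, the mitochondrial carrier gene ucp2 at 0.77 ± 0.07 and acadm at 0.44 ± 0.04, while the peroxisomal gene ehhadh (-0.55 ± 0.09) and acsl1a (-0.17 ± 0.05), both named after their values were seen, fell. Hypoxia genes rose in 10 of 24 members, or 11 adjusted over the list alone (camera adjusted p = 1.1e-08, and 0.00226 with an estimated correlation). They included the glycolysis genes aldocb (0.26 ± 0.04) and pfkfb4a (0.46 ± 0.06) and hif1al (0.83 ± 0.07). Epidermal genes fell in 18 of 29 members and rose in 1, or 19 and 1 adjusted over the list alone (camera adjusted p = 1.34e-09, and 0.0223 with an estimated correlation). Examples were krt15 at -0.94 ± 0.09, icn2 at -1.08 ± 0.09 and cldne as the member that rose (0.55 ± 0.05). Ionocyte genes rose in 11 of 21 members and fell in 2, or 12 and 3 adjusted over the list alone (camera adjusted p = 1.69e-06, and 0.0213 with an estimated correlation). Among them slc12a10.2 was at 1.04 ± 0.06 and rhcgb at 0.84 ± 0.09, and trpv6 (-0.51 ± 0.09) and the sodium proton exchanger gene slc9a3.1 (-0.51 ± 0.15), both named after their values were seen, fell.

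The circadian list passed in OCT20 with 17 of 32 members higher and 8 lower, or 18 and 8 adjusted over the list alone (adjusted p = 0.0865 with an estimated correlation). The clock gene per1a rose (1.51 ± 0.11, adjusted p = 4.25e-09), as did tefa, per2 (0.97 ± 0.05) and cry2 (0.88 ± 0.06), while arntl1a fell (-0.51 ± 0.05). Cell cycle genes fell in 17 of 28 members, also 17 adjusted over the list alone (adjusted p = 0.437 with an estimated correlation), such as bub1 (-0.70 ± 0.13), tpx2 (-0.69 ± 0.14) and top2a (-0.69 ± 0.14). On the low and the high side of the October division bub1 was at -0.51 ± 0.13 and -0.99 ± 0.12, tpx2 at -0.49 ± 0.16 and -0.97 ± 0.15, and top2a at -0.49 ± 0.17, not called (adjusted p = 0.0728), and -0.96 ± 0.17. Photoreceptor genes fell in 19 of 43 members and rose in 3, or 23 and 4 adjusted over the list alone (adjusted p = 0.132 with an estimated correlation). The members that fell included the opsin genes opn1sw1 (-0.95 ± 0.08), opn1sw2 (-0.86 ± 0.10) and opn1mw1 (-2.33 ± 0.27), and the cone arrestin gene arr3b, named after its values were seen, was a member that rose (0.88 ± 0.14). Heat shock genes rose in 9 of 24 members, or 11 adjusted over the list alone (adjusted p = 0.221 with an estimated correlation), with chordc1a at 0.75 ± 0.10 and hsp90aa1.2 at 1.15 ± 0.20. Red cell and haem genes rose in 8 of 26 members, or 12 adjusted over the list alone, led by tspo (1.23 ± 0.05), fech (0.92 ± 0.08) and alas1 (1.36 ± 0.12; list adjusted p = 0.299 with an estimated correlation). Unfolded protein and ATF4 genes rose in 7 of 26 members, or 8 adjusted over the list alone, such as atf3 (1.17 ± 0.18) and sesn2 (0.67 ± 0.15; list adjusted p = 0.132 with an estimated correlation). Immediate early genes rose in 10 of 28 members and fell in 1, or 12 and 1 adjusted over the list alone, with fosl1a at 1.48 ± 0.15 and ccn2a at 0.53 ± 0.07 (list adjusted p = 0.432 with an estimated correlation). Skeletal muscle genes fell in 13 of 46 members and rose in 2, or 16 and 2 adjusted over the list alone, with mybpc2b at -0.71 ± 0.07 (list adjusted p = 0.415 with an estimated correlation). Genes of the glucocorticoid list rose in 6 of 20 members, also 6 adjusted over the list alone (adjusted p = 0.451 with an estimated correlation). They included per1a, glula (0.50 ± 0.06) and the metal-binding gene mt2 (0.60 ± 0.10), while fkbp5 was not called (0.34 ± 0.27, adjusted p = 0.453).

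**Figure D3:**
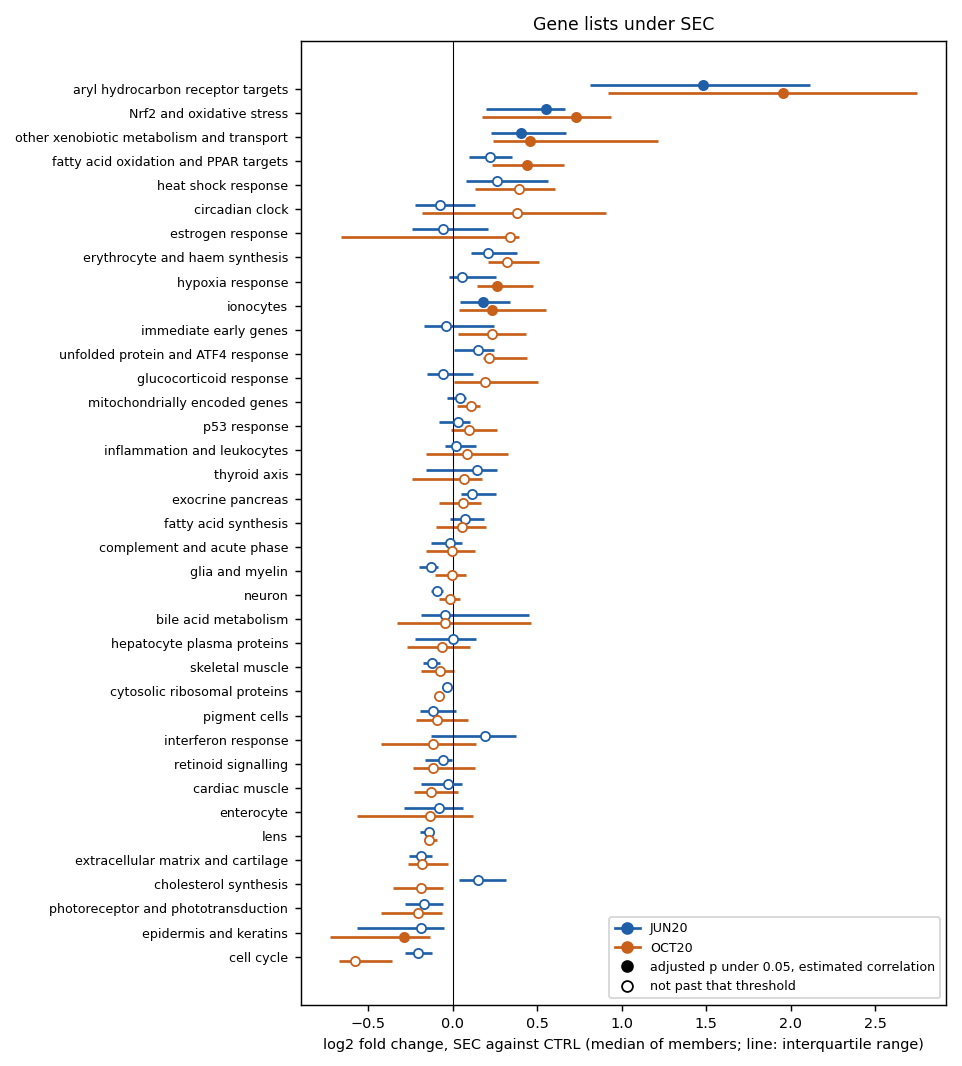
Median log2 fold change of SEC against CTRL over the tested members of each of the 37 gene lists (points), with the interquartile range of the members (lines), in JUN20 (blue) and OCT20 (orange), and filled points for lists past an adjusted p of 0.05 with an estimated correlation. The aryl hydrocarbon receptor list had medians of 1.48 and 1.95, the epidermal list -0.19 and -0.291.

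Smaller groups completed the October lists. Mitochondrially encoded genes rose in 4 of 13 members, or 5 adjusted over the list alone, with mt-co1 at 0.25 ± 0.04 (list adjusted p = 0.506 with an estimated correlation), in libraries where mitochondrial ribosomal RNA was 3.16% of counts with SEC and 2.76% in CTRL. Ribosomal protein genes fell in 11 of 75 members, or 26 adjusted over the list alone, with rpl23a at -0.14 ± 0.04 (list adjusted p = 0.432 with an estimated correlation). Enterocyte genes fell in 13 of 32 members and rose in 5, or 14 and 6 adjusted over the list alone, with ada at -0.63 ± 0.07, mogat2 at -0.94 ± 0.11 and fabp6 at 0.55 ± 0.09 (list adjusted p = 0.561 with an estimated correlation). Lens genes fell in 4 of 49 members, or 1 adjusted over the list alone, with crybb3 at -1.10 ± 0.26 (list adjusted p = 0.535 with an estimated correlation). Extracellular matrix genes fell in 2 of 38 members and rose in 1, with none adjusted over the list alone, and col2a1b was at -0.35 ± 0.11 (list adjusted p = 0.761 with an estimated correlation), a call lost when any of several libraries was left out. The p53 list rose in 3 of 16 members, also 3 adjusted over the list alone, with gadd45aa at 1.04 ± 0.11 and cdkn1a at 0.85 ± 0.24 (list adjusted p = 0.432 with an estimated correlation). The lists that did not pass had camera adjusted p from 0.0616 for cardiac muscle to 0.987 for the thyroid axis. They were estrogen, retinoid, cholesterol synthesis, fatty acid synthesis, bile acid, exocrine pancreas, hepatocyte, complement, inflammation, interferon, neuron, glia and pigment cell genes besides those named. In the estrogen list 2 of 8 members rose and 1 fell, and vtg1 was at -1.05 ± 0.50 (adjusted p = 0.167). The indicator gene hsp70l was at 0.57 ± 0.46 (adjusted p = 0.448). Median and mean differed in sign for the thyroid list (median 0.0668, mean -0.0095, test down) and the bile acid list (median -0.0486, mean 0.0681, test up). With the preset correlation 19 of 37 lists passed in JUN20 and 22 in OCT20, and 4 and 7 passed with an estimated one. Of 100 divisions of the same 10 libraries into groups of 5, the real one included, 18 gave as many lists as the real one in JUN20 and 7 in OCT20 at the preset correlation, where with an estimated one no other division reached the real count. Most of the other divisions that did so at the preset correlation kept all but 1 SEC library together, and so much of the real contrast. The test fry, which asks whether a list's members move on balance one way and does not compare them with other genes, passed 17 lists in JUN20 and 20 in OCT20, and its mixed form, which counts change in either direction, passed 27 and 33.

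The effects of the June and the October extract were compared gene by gene, with no library shared between them. Both extracts raised cyp1a, cyp19a1b, cyp1c1, hebp2, cyp1b1, ahrra, cry5, tspo, porb and foxq1a, the 10 genes with the smallest p in both. In JUN20 porb was at 0.84 ± 0.05. Of 1368 genes higher in JUN20, 893 (65.3%) were higher in OCT20 as well, where independent lists would share 130.5. Of 1133 genes lower in JUN20, 581 (51.3%) were lower in OCT20, where independent lists would share 96.2 (one-sided Fisher's exact test, log10 p of -626 and -337). In all 1474 genes were called in the same direction in both and 14 in opposite directions. Across the 23121 genes the log2 changes correlated with Pearson's r of 0.562 and Spearman's rho of 0.486, and across the 5181 genes called in either campaign with 0.789 and 0.778. Genes are not independent replicates, so no p is given for these correlations, and the Fisher test takes genes as independent. The slope of OCT20 on JUN20 changes was 0.708 across all tested genes and 1.15 across the called genes, a set to which OCT20 gave more calls than JUN20.

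**Figure D4:**
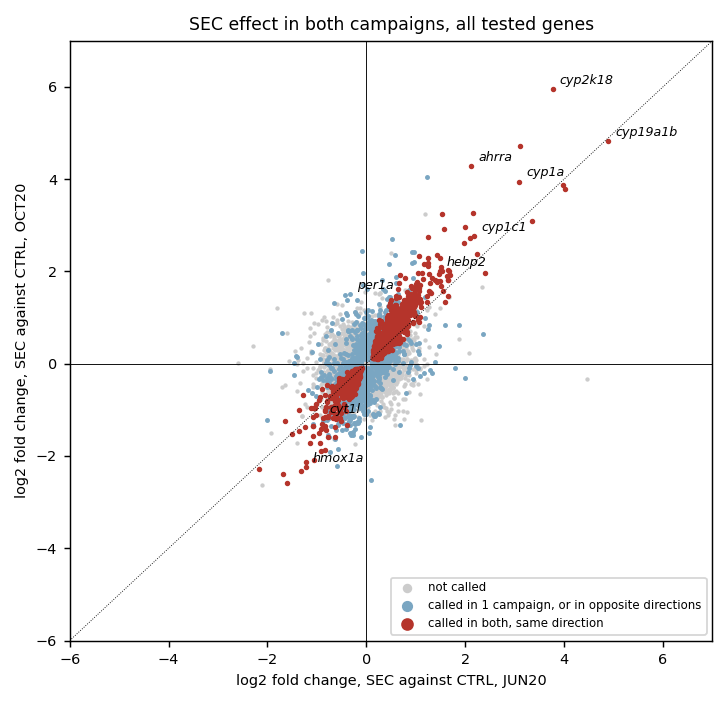
Log2 fold change of SEC against CTRL in JUN20 (horizontal) and OCT20 (vertical) for the tested genes, 1 point per gene, with the dotted line at equal change, red for the 1474 genes called in both in the same direction, blue for genes called in 1 campaign or in opposite directions and grey for the rest. cyp19a1b lies near the dotted line at 4.90 and 4.82, and per1a lies below 0 in JUN20 (-0.33) and above 0 in OCT20 (1.51).

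Whether the extract's effect differed between campaigns was tested directly, as the OCT20 effect minus the JUN20 effect. Clock genes and receptor targets had the strongest evidence of a more positive effect in OCT20. The genes with the smallest p in that direction were per1a (1.84 ± 0.15, adjusted p = 2.7e-06), ahrra (2.15 ± 0.20, adjusted p = 7.05e-06), cyp1a (0.86 ± 0.09), the clock repressor gene ciarta (1.03 ± 0.10) and the nuclear receptor gene nr1d2b (0.52 ± 0.06). With a more negative effect they were impdh1b (-0.35 ± 0.05), rx2 (-0.94 ± 0.16), the basement membrane gene nid1a (-0.39 ± 0.06), baiap2l1a (-0.61 ± 0.10) and the annexin gene anxa1c (-1.29 ± 0.22). All of these fell in OCT20; in JUN20 rx2 fell less (-0.38 ± 0.11) and baiap2l1a rose (0.23 ± 0.07), while impdh1b, nid1a and anxa1c were not called. The aromatase gene cyp19a1b did not differ past the threshold, with a difference of -0.07 ± 0.16 (adjusted p = 0.931), nor did hmox1a (-1.01 ± 0.28, adjusted p = 0.0948). Between the SEC groups themselves, OCT20 minus JUN20, ahrra was at 0.05 ± 0.11, cyp1a at 0.10 ± 0.06 and per1a at 0.14 ± 0.10. Between the control groups the same genes were at -2.10 ± 0.17, -0.76 ± 0.06 and -1.70 ± 0.11. Of 23121 genes 239 passed, 182 with a more positive and 57 with a more negative effect in OCT20. The list tests passed 17 of 37 lists, and 4 with an estimated correlation. These were the circadian clock, with 13 of 32 members higher, or 17 with 2 lower adjusted over the list alone (adjusted p = 0.0108), aryl hydrocarbon receptor targets with 5 of 11, or 8 adjusted over the list alone (adjusted p = 0.000191). They also held hypoxia with 2 of 24, or 9 and 1 adjusted over the list alone (adjusted p = 0.0108), and Nrf2 with 2 of 24, or 8 and 1 adjusted over the list alone (adjusted p = 0.023). Among the clock members with a more positive effect in October were cry5 (0.72 ± 0.08), per2 (0.51 ± 0.08) and tefa (0.56 ± 0.06). The lists that passed with the preset correlation alone were, higher, xenobiotic metabolism, glucocorticoid, fatty acid oxidation, unfolded protein, neuron, glia, immediate early, red cell and haem, and mitochondrially encoded genes, and, lower, cholesterol synthesis, cell cycle, epidermal and ribosomal protein genes (adjusted p from 0.0772 to 0.715 with an estimated correlation). DESeq2 called 606 genes, a fit with the October division as a term 629, with 3 of these 4 lists and Nrf2 no longer past (adjusted p = 0.051), and fits with 1 library left out 134 to 330. Scaling by library totals alone turned the balance to 122 with a more positive and 135 with a more negative effect.

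**Figure D5:**
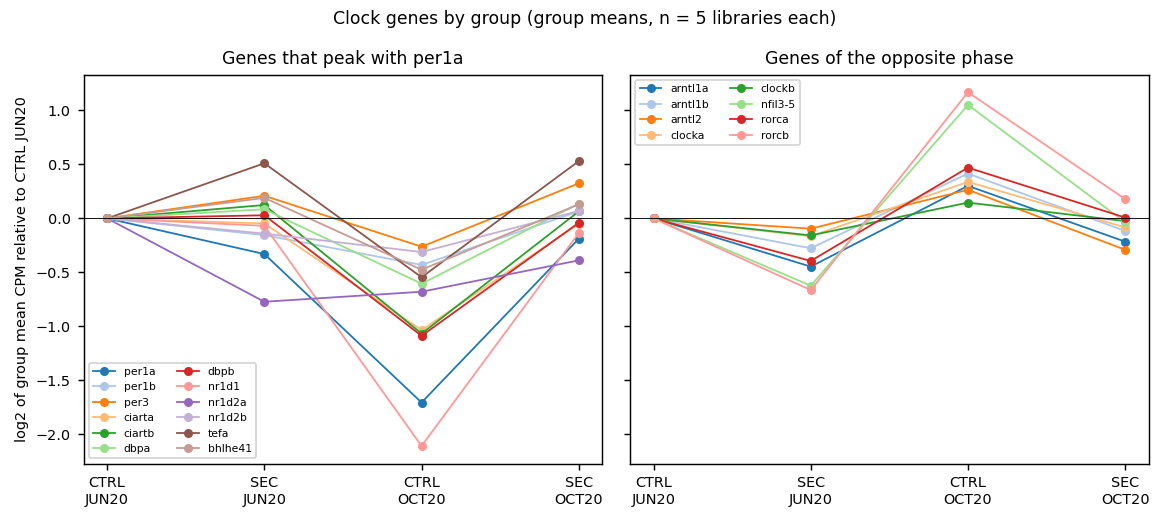
Log2 of the group mean CPM relative to CTRL JUN20 for 12 clock genes that peak with per1a (left) and 8 genes of the opposite phase (right) in the 4 groups, 1 line per gene, each point a mean of 5 libraries. Between the control groups all 12 genes on the left were lower in OCT20, with a median of -0.642, and between the SEC groups their median difference was 0.0364.

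The control groups of both campaigns were compared to show how far the experiments differed without extract, as CTRL OCT20 minus CTRL JUN20; campaign and batch cannot be told apart here. The genes with the smallest p on the higher side in October were the cold-inducible RNA-binding protein gene cirbpb (0.38 ± 0.04, adjusted p = 2.34e-06), the chromatin protein gene hmgb1a (0.39 ± 0.04), the RNA helicase gene ddx3xa (0.39 ± 0.05), tmigd1 (0.69 ± 0.09) and the RNA-binding protein gene fus (0.34 ± 0.04). On the lower side they were per1a, ciarta (-1.04 ± 0.07), cyp1c1 (-0.70 ± 0.05), cyp1a and ahrra. Heat shock genes fell in 13 of 24 members, or 19 adjusted over the list alone (camera adjusted p = 4.05e-16, and 0.0648 with an estimated correlation), such as dnajb1a (-0.98 ± 0.08), chordc1a (-1.01 ± 0.10) and hsp90aa1.2 (-1.67 ± 0.20). Aryl hydrocarbon receptor targets fell in 6 of 11 members, also 6 adjusted over the list alone (camera adjusted p = 1.6e-07, and 0.00107 with an estimated correlation). Immediate early genes fell in 11 of 28 members, or 15 adjusted over the list alone, with fosab at -1.20 ± 0.22 and nr4a1 at -1.09 ± 0.18 (list adjusted p = 0.471 with an estimated correlation). Clock genes fell in 15 of 32 members and rose in 5, or 16 and 8 adjusted over the list alone (list adjusted p = 0.513 with an estimated correlation), with nr1d1 at -2.10 ± 0.20 and arntl1a at 0.30 ± 0.05. The other lists that passed with the preset correlation were, lower, xenobiotic metabolism, unfolded protein, cell cycle, extracellular matrix, red cell and haem, and pigment cell genes, and, higher, lens, cardiac muscle and ribosomal protein genes (adjusted p from 0.471 to 0.748 with an estimated correlation). The list members named in this comparison were picked after their values were seen. Of 23121 genes 1341 passed, 654 higher and 687 lower in October, 33 and 67 of them by at least 2-fold. The count was 565 in a fit of the control libraries alone, 2063 with DESeq2 and 2205 with the October division as a term. It was 704 without CTRL OCT20 replicate 1 and 2410 without CTRL OCT20 replicate 2.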

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

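The tests of the October division, the clock genes, the heat shock genes and the share of the control groups in the difference were chosen only after those results had been seen, and the limit for the other divisions of the JUN20 libraries was set after its counts were known.

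A direct test found that the effect of SEC differed between campaigns in 239 genes. Among the genes named in the text, these rose in OCT20 and had a more positive effect there than in JUN20, as log2 differences: cyp1a 0.86, cyp1c1 0.58, hebp2 0.53, cyp1b1 0.63, ahrra 2.15, cry5 0.72, tspo 0.40, per1a 1.84, abcc2 0.67, cyp2k18 2.19, cyp2n13 0.58, atp1a1a.3 0.32, acadvl 0.32, porb 0.56, tefa 0.56, ucp2 0.51, per2 0.51, cry2 0.56, aldocb 0.21, chordc1a 0.58, glula 0.55, ciarta 1.03, nr1d2b 0.52, nr1d1 2.04, cry-dash 0.56, xpc 0.51 and abcb11a 1.09. The effect was more negative in OCT20, where all of them fell, for krt18a.2 (-0.52), slc5a1 (-0.58), ms4a17a.16 (-0.62), impdh1b (-0.35), rx2 (-0.94), nid1a (-0.39), baiap2l1a (-0.61), anxa1c (-1.29) and lyz (-0.57).

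A single library lay far from the other 4 of its group for 28 of 552 combinations of a named gene and a group, or 5.07%, where chance alone gives about 1 in 20. In CTRL JUN20 these were pkp1b in replicate 3 (15.97 CPM), ehhadh in replicate 4 (16.1 CPM), and nr4a1 (43.7 CPM) and cpdp (33.2 CPM) in replicate 2, each the highest. In SEC JUN20 they were rhcgb (43.1 CPM) and ada (210 CPM) as highest and hsp70.2 (17.3 CPM) and dnajb1a (15.1 CPM) as lowest in replicate 5, and fech (10.7 CPM) and col2a1b (540 CPM) as highest and il1b (0.296 CPM) as lowest in replicate 2. In CTRL OCT20 they were ahrra (0.862 CPM) and guca1g (6.08 CPM) as highest and cldne (65.7 CPM) as lowest in replicate 5, fabp6 (166 CPM) and hmgb1a (235 CPM) as highest in replicate 4, and tefa (141 CPM), hsp90aa1.2 (97.5 CPM), serpinh1b (39.5 CPM) and c9 (100.4 CPM) as highest in replicate 2. In SEC OCT20 they were ahrra in replicate 3 (9.02 CPM) as lowest, nfe2l2a (324 CPM) as lowest and impdh1b (39.9 CPM) as highest in replicate 1, mybpc2b (93.7 CPM) and xpc (66.9 CPM) as highest in replicate 4, and hif1al (441 CPM) as highest and hsp90aa1.2 (105 CPM) and neil1 (22.9 CPM) as lowest in replicate 5.

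The main counts were set against 100 divisions of the same libraries into groups of the same sizes, the real one included, to ask whether chance can be excluded. A count as large as the real one came from 1 division in JUN20 (2501 genes, highest other 3), 1 in OCT20 (4168, highest other 2827), 2 for the difference (239, highest other 3241), 1 between controls (1341, highest other 1179) and 1 for genes called in both campaigns (1474, highest other 0). For lists at the preset correlation it came from 18 divisions in JUN20 (19 lists, highest other 26) and 7 in OCT20 (22, highest other 26). Most of these other divisions, including both with 26 lists, kept all but 1 SEC library of the campaign together. They therefore held much of the real contrast, so these counts of lists cannot exclude chance and do not show what chance gives. With an estimated correlation a count as large as the real one came from 1 division each (4 lists with highest other 0, and 7 lists with highest other 2). The divisions for the difference exchanged libraries between campaigns, within CTRL and within SEC. The campaigns differed in both (1341 genes between controls, 2770 between SEC groups), which widens the spread of most such mixed groups. The count of 2 divisions therefore cannot exclude chance for the 239 genes. The division of the difference that gave 3241 genes exchanged all SEC libraries between campaigns, with CTRL JUN20 replicate 3 and CTRL OCT20 replicate 4, so it points to structure between campaigns rather than to chance. The OCT20 division that followed the 5 October genes gave 3523 genes and 17 lists, which also points to structure within the October libraries. The divisions for genes called in both campaigns relabelled both at once. Other divisions of the JUN20 libraries called at most 3 genes, which leaves almost none to share. That comparison therefore cannot tell whether the extracts share more genes than their numbers of calls would give.

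The October libraries fell into a low and a high side by BX004857.1, si:ch1073-464p5.5, si:dkey-125e8.3, si:dkey-269o24.1 and zgc:194659, genes taken only where each side held both groups, so the exposure as their source was not tested. Against depth, the low side had a mean of 36.8 M counts and the high side 33.3 M (exact permutation p = 0.31). Parents that differ in these genes could give such sides, and 2 of the 5 genes also fell under 5% of the other libraries' median in June libraries of the SEC group. These were BX004857.1 and si:dkey-125e8.3, both at 0 counts in SEC JUN20 replicates 2 and 5, so they do not count separately. In the June controls si:dkey-269o24.1 was at 0.172 CPM in replicate 2, against 1.46 to 6.88 in the other June libraries, which just missed the 5% limit. The sides differed in more than these genes, since they matched the sign of the first component of the deviations from group means (44.3% of the variance) in 10 of 10 October libraries, and no source of that was tested. No label names the parents of a pool, so this stays open.

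Clock genes that peak with per1a were lower in the October controls than in the June controls, 12 of 12, with a median of -0.642, and 5 of 8 genes of the opposite phase were higher, with a median of 0.381. These 20 genes were picked from the clock list after its result was seen. Other tested members, such as per2 and cry2, were left out, so the counts hold for the picked genes only. Between the SEC groups the median difference was 0.0364 for the 12 genes. This argues against another clock time for the whole October campaign only if the October extract did not itself move these genes. Their median change with SEC in OCT20 was 0.864, so the comparison cannot exclude a shift of the campaign that the extract offset. For the 8 genes the difference between the SEC groups was 0.195, which leaves another clock time open for these. Of 20 clock genes of both phases 19 moved in opposite directions with SEC in OCT20, as they could if October controls and October SEC pools had been collected at different clock times. The extract might instead move the clock: in JUN20 2 of the 12 genes rose and 3 fell, which argues against the extract raising these in both campaigns and not against an effect of the October extract alone, while 5 of the 8 genes fell in JUN20 (median -0.333) and 8 of 8 in OCT20, so an extract lowering these in both campaigns stays open. The clock time of collection is not given in the sources used here.

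Heat shock genes were lower in the October controls for 13 of 24 members (median -0.683 over the 24 and -1.13 among the 13), and 12 of the 13 were also lower between the SEC groups (median -0.568 over the 24 and -0.714 among the 13), as a condition of the whole campaign such as temperature could give. A single control library was not the source, since at least 11 of the genes still passed whichever control library was left out. cirbpb, a gene raised by cold, was higher in October by 0.38 between controls and 0.27 between SEC groups. The labels give 28.5 °C water for all 4 groups, temperature as it was reached during each campaign was not tested, and no biological explanation was tested because the extract does not divide these groups.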

How the results depend on the processing

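The October division as a term, and fits within its sides, were chosen after seeing the data; all other settings were planned. Under the settings with no block and no single library left out, the count in JUN20 (2501) lay between 2229 and 3681. The count of genes called in both campaigns (1474) lay between 1334 and 2133 under these settings. The count in OCT20 (4168) was 2763 with only the libraries compared in the fit, where that setting raised JUN20 to 3666, so which campaign had more calls depended on it. The main fit gave all groups a shared estimate of the spread. The highest chi-squared per degree of freedom of a pair was 45 in CTRL OCT20 and 19.9 in SEC OCT20. It was 12.2 in CTRL JUN20 and 14.7 in SEC JUN20. Whether this spread was the cause was not tested. For the difference (239 genes) DESeq2 gave 606 and the October term 629. Between controls (1341 genes) DESeq2 gave 2063, only the libraries compared 565 and the October term 2205; the cause was not tested. Lists past the threshold fell from 19 to 4 in JUN20 and from 22 to 7 in OCT20 with an estimated correlation, and were 6 and 7 with that and the October term. Library totals in place of TMM moved the split of higher and lower genes from 1368 and 1133 to 1800 and 724 in JUN20, from 2205 and 1963 to 1985 and 2271 in OCT20, from 182 and 57 to 122 and 135 for the difference and from 654 and 687 to 491 and 786 between controls. Leaving out 1 library gave 1826 to 2216 genes in JUN20, 3394 to 4447 in OCT20, 134 to 330 for the difference, 704 to 2410 between controls, 1184 to 1558 in both, and 18 to 21 and 19 to 25 lists. The count moved by more than 1.5 times for the difference without CTRL JUN20 replicate 3, SEC JUN20 replicates 2 and 3 or CTRL OCT20 replicate 3, and between controls without CTRL JUN20 replicates 1, 2 and 3 or CTRL OCT20 replicates 1, 2 and 3; the cause was not tested. With the replicate number as a block the counts were 1759 in JUN20, 3338 in OCT20, 116 for the difference and 1101 in both, with 21 and 22 lists. Libraries of the same number did not deviate together (r from -0.0789 to 0.119 in JUN20 and from -0.555 to 0.342 in OCT20, own number best in 0 of 5 each), so the numbers were not taken as pairs. Of 611 values of named genes none reversed its direction past the threshold under any setting, and 141 lost or gained a call in at least 1. Simulated changes of 0.5 on the log2 scale were missed more often than larger ones, which limits what this depth and spread can show.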

Other observations

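Some genes, most of them outside the fixed lists, were called higher with both extracts; they were picked because of their values, so nothing follows for DNA repair genes as a group. In JUN20 and OCT20, the DNA photolyase-like gene cry-dash rose by 0.75 ± 0.07 and 1.31 ± 0.07, the cyclobutane dimer photolyase gene cpdp by 0.64 ± 0.06 and 0.75 ± 0.06, the damage sensor genes xpc by 0.85 ± 0.06 and 1.36 ± 0.06 and ddb2 by 0.49 ± 0.09 and 0.83 ± 0.09, and the glycosylase gene neil1 by 0.42 ± 0.06 and 0.58 ± 0.06 (log2 ± SE, n = 5 per group). The photolyase family gene cry5 and the light-induced gene per2 (0.46 ± 0.05 and 0.97 ± 0.05), both of the circadian clock list, and the genes lonrf1 (0.53 ± 0.07 and 0.92 ± 0.07) and lonrf1l (0.69 ± 0.08 and 1.09 ± 0.08) rose as well. The repair genes ercc1, mgmt, polk and ddb1 were called in neither campaign, with polk at -0.27 ± 0.10 in OCT20 (edgeR adjusted p = 0.0598).

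Genes of bile acid transport and synthesis, a list that did not pass as a whole, moved in opposite directions, and the members were picked after their values were seen. The ileal uptake transporter gene slc10a2 rose by 0.72 ± 0.12 in JUN20 and 0.73 ± 0.12 in OCT20, the bile acid receptor gene nr1h4 by 0.32 ± 0.07 and 0.42 ± 0.07 and the export pump gene abcb11a by 0.65 ± 0.17 and 1.75 ± 0.18. The synthesis gene cyp7a1 fell, at -0.46 ± 0.12 and -0.65 ± 0.12, and the repressor gene nr0b2a fell in OCT20 (-1.34 ± 0.20) and was at -0.36 ± 0.19 in JUN20 (edgeR adjusted p = 0.237). The immune and digestive genes that follow were also picked after their values were seen, and the inflammation and complement lists passed in neither campaign. In JUN20 and OCT20, stat1b was at 0.94 ± 0.24 and 1.15 ± 0.24 and the protease gene prss60.1 at 1.28 ± 0.23 and 1.75 ± 0.24. Called in OCT20 alone were il1b (-0.03 ± 0.24 and 0.99 ± 0.25), the complement gene c9 (-0.35 ± 0.14 and -0.61 ± 0.14) and the lysozyme gene lyz (0.14 ± 0.09 and -0.43 ± 0.09).

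Some genes stood apart in a single library. SEC OCT20 replicate 5 alone was high for the immune genes irg1l (23.3 CPM, other October libraries 1.13 to 2.21) and ccl20b (3.96 CPM, others 0.346 to 0.946) and for plekhs1 (14.4 CPM, others 0.898 to 2.99) and urgcp (13.3 CPM, others 1.15 to 3.09). SEC JUN20 replicate 1 was low for rrm2 (ENSDARG00000078069, 1.69 CPM, others 22.9 to 53) and actc1a (ENSDARG00000076126, 4.19 CPM, others 38.2 to 80.9), both symbols shared by more than 1 gene and so uncertain. SEC OCT20 replicate 3 had 0 counts of CR788316.4, where the other October libraries had 1.77 to 16.6 CPM.

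One hypothesis was that the 239 genes whose SEC effect differed between campaigns differed because the control groups did. The control groups differed by more than the SEC groups in 99 of these genes (41.4%), and the median absolute difference was 0.201 between controls and 0.285 between SEC groups. The hypothesis was therefore not borne out for the set as a whole, although it could hold for genes such as ahrra, cyp1a and per1a, whose SEC groups were alike.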
